A study of Mus musculus with 15 samples.

How the data were processed

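Gene expression was measured in 2 related mouse mammary carcinoma lines, 4T1 and 4TO7. Per the labels, 4T1 cells carried a lentiviral pLKO vector with a scrambled hairpin or with either of 2 hairpins against Tm4sf1 (shTM4SF1-1 and shTM4SF1-5, called hairpin 1 and hairpin 5 here). The 4TO7 cells carried the retroviral vector pBabepuro, empty or with TM4SF1. Each of the 5 groups held 3 arrays that the labels call biological replicates, 15 in all. Total RNA was extracted with Trizol and turned into biotinylated cRNA, per the labels' protocols, and hybridised to Illumina mouse BeadChips.

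The deposited matrix gave, per the file headers, the mean bead intensity of each of 25697 probes on a linear scale, neither normalized nor background-subtracted. It also gave a standard error of that intensity, the number of beads, and a detection p-value of each probe, per the file headers. The submitters' processing notes name GenomeStudio, whose version is not given in the sources used here. A second table of the authors' deposited values held intensity after background subtraction and quantile normalization, as judged from the values themselves: ranks within each array matched those of the unnormalized signal (r = 1), array medians lay between 8.34 and 8.45, and the lowest value was -18.46. The scale was linear and the values were not centred. The method behind them is not given in the sources used here. Columns were matched to samples by their names, and 0 columns belonged to no sample.

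The analysis started from the unnormalized intensities. Background was corrected with limma's normexp method, with the negative control distribution inferred from the detection p-values, and an offset of 16 was added. Arrays were quantile normalized and put on the log2 scale. Probes with a detection p under 0.01 on at least 3 arrays were kept, 11109 of them. Gene symbols came from the platform annotation of 2016, in which 23978 probes had 1 symbol, 0 had several and 1719 had none. Of the named probes, 23962 matched the RefSeq gene table of GRCm38.p6, and 0 symbols changed. The brightest probe of each symbol was used, which left 8228 genes (7576 named and 652 unnamed probes). Other probes of a gene were compared with it. Named genes are given under their current symbols, and probes from near-identical paralogs cannot be told apart by their annotation.

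A group-means model was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, so that the 5 groups shared an estimate of the spread (10 residual and 16.07 prior degrees of freedom, with a mean-variance trend). All p-values of single genes are from limma and are two-sided. They were adjusted by the Benjamini-Hochberg method within each comparison, and genes past an adjusted p of 0.05 were called. The comparisons were each hairpin against scramble, hairpin 1 against hairpin 5, TM4SF1 against empty vector in 4TO7, and empty-vector 4TO7 against scramble 4T1. Genes called in the same direction with both hairpins were counted as shared, and shared genes called in the opposite direction in 4TO7 with TM4SF1 as reciprocal. An exact permutation of 3 arrays against 3 cannot go below p = 0.1, so no permutation test of single genes was used. The number of arrays limits the precision. The median standard error of a log2 fold change was 0.13.

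A probe with no detection on any array of a group had only a bound there. For such genes the fold is written as "at least", from the mean of the brighter group and, in the dimmer group, the higher of the probe's own value and the lowest detected value of each array. The 23 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Counts within a list are given over all genes tested and adjusted over the list alone.

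Genes named in the text followed a rule set before the data were examined. For each hairpin and for TM4SF1 in 4TO7 it took up to 10 rises and 10 falls, the largest among called genes whose groups did not overlap. It took the 10 shared genes each way with the largest smaller change, and 5 each way for hairpin 1 against hairpin 5 and for the lines. In each list it took up to 4 called members, or the member with the largest change where none was called. Tm4sf1 was always named. Unnamed probes, predicted genes and pseudogenes were skipped.

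Alternatives set beforehand were no background correction, an offset of 50, the authors' normalized table, cyclic loess or median scaling, other detection filters, all probes, only the compared arrays, no variance trend, array weights, the replicate number as a block, and each array left out in turn. The brightness of the array as a covariate, the omission of the dimmest array of each group, and the target family list without Tm4sf1 were chosen after seeing the data. Every other split of the compared arrays was fitted as well, or 100 splits, the real one included, for shared and reciprocal genes. Slide was not analysed here as a batch. The model fit and the list test were tried on 20 simulated datasets of 8228 genes for each comparison simulated. Known shifts were added to simulated log2 values, so background correction, normalization, the detection filter and the choice of probe were not checked. For hairpin 1 against scramble limma called 57.8% of genes planted at a log2 change of 0.5 and 93.3% of those at 1. For TM4SF1 against vector the shares were 54.7% and 92.9%. In the hairpin 1 simulation, 4.72% of calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.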

Results

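Transcript levels were compared in 4T1, a mouse mammary carcinoma line that metastasises spontaneously, and 4TO7, a sister line from the same tumour that disseminates but seldom forms overt metastases. Tm4sf1, which encodes a membrane protein of the L6 family related to the tetraspanins, was knocked down in 4T1 with either of 2 hairpins and introduced into 4TO7 with a retrovirus. There were 3 arrays in each of 5 groups. Between 9436 and 10703 of 25697 probes were detected on an array, and the mean signal of an array ran from 222 to 418.6. Across genes, normalized arrays of a group correlated at r = 0.9866 to 0.9947, arrays of different groups of a line at 0.9822 to 0.993, and arrays of different lines at 0.9224 to 0.9345. The labels call the replicates biological, but whether cultures were grown separately is not given in the sources used here. The p-values therefore measure the spread between these arrays.

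The targeted gene was examined first. Tm4sf1 (probe ILMN_2462650) averaged 8.07 on the log2 scale with scramble (SD 0.0831, n = 3), 6.94 with hairpin 1 (SD 0.163, n = 3) and 6.58 with hairpin 5 (SD 0.567, n = 3). It fell 2.19-fold with hairpin 1 (log2 fold change -1.13, SE 0.194, adjusted p = 4.91e-04, limma) and 2.81-fold with hairpin 5 (-1.49, SE 0.194, adjusted p = 1.87e-05, limma). The size depends on the handling of background, since without background correction the log2 changes were -0.73 and -0.90. Tm4sf1 was detected on every array of both knockdowns. In 4TO7 its mean was 8.27 with the empty vector (SD 0.413, n = 3) and 8.41 with TM4SF1 (SD 0.118, n = 3), a log2 difference of 0.14 (SE 0.194, adjusted p = 0.933, limma), so the arrays labelled TM4SF1 showed no detectable gain at this probe. Whether the probe lies within the transduced sequence is not given in the sources used here, so it may not report the introduced transcript, and directions drawn from the 4TO7 comparison rest on the labels. Without vector replicate 2 the 4TO7 difference was -0.075.

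**Figure D1:**
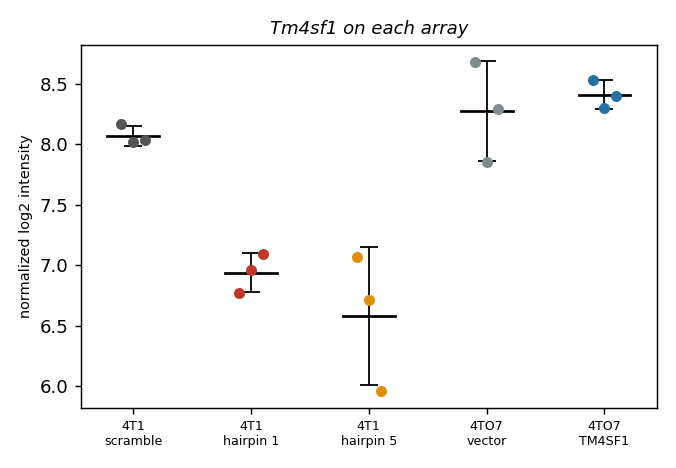
Normalized log2 intensity of Tm4sf1 (vertical axis) on each of the 15 arrays by group (horizontal axis), with points for arrays, thick bars for group means and error bars for 1 SD (n = 3). The arrays with either hairpin lie below all scramble arrays, while the vector and TM4SF1 arrays of 4TO7 overlap.

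With hairpin 1, the largest rises were in Prl2c3 and Prl2c4, which encode proliferins, placental hormones of the prolactin family. Prl2c3 rose by 2.22 (SE 0.126, adjusted p = 3.84e-12, limma, n = 3 against 3) and Prl2c4 by 2.18, although near-identical paralogs make it uncertain which proliferin each probe reads. The glutathione transferases Gsta1 (1.51, adjusted p = 9.45e-07) and Gsta2 (1.04, adjusted p = 4.15e-04), the urea transporter Slc14a1 (1.29) and the P-type ATPase Atp13a4 (1.27) also rose. So did 3 genes linked to amino acid and folate stress, Chac1 (1.16, SE 0.0829), Ddit3 (1.08, SE 0.136) and the mitochondrial folate enzyme Aldh1l2 (1.01). Havcr2, which encodes the immune receptor TIM-3, was at least 1.21-fold higher (adjusted p = 0.00145). Among the falls were Plvap (-1.41, adjusted p = 1.61e-06), a component of endothelial diaphragms, the transcription factor gene Tfap2c (-1.37) and the sulfotransferase gene Chst1 (-1.34). Pi16 (-1.32), Trp53i11 (-1.32), Mustn1 (-1.10) and Shisa2 (-1.04) fell as well, and Ecrg4 was at least 1.63-fold lower (adjusted p = 7.72e-04). Lcn2, which encodes a siderophore-binding lipocalin, fell by 1.23 (SE 0.0775, adjusted p = 1.84e-11). Extra probes moved the same way but by less for Tfap2c (-0.51), Mustn1 (-0.46), Slc14a1 (1.05 and 0.60) and Aldh1l2 (0.44). With hairpin 1, Pi16 was detected on 1 of 3 arrays and Tfap2c, Chst1, Trp53i11 and Mustn1 on 2 of 3, and Gsta2 was detected on 2 of 3 scramble arrays. The sizes of these changes depend on the background.

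In all, 480 of 8228 genes (5.83%) passed an adjusted p of 0.05 in limma with hairpin 1, of which 248 rose and 232 fell, and 25 had a log2 change of 1 or more. The arrays of the 2 groups did not overlap for 25.1% of genes, against 10% by chance. The count was 290 without scramble replicate 1, 281 without scramble replicate 3, 289 without hairpin 1 replicate 2 and 273 without hairpin 1 replicate 3. It was 318 with no detection filter, and 183 without the dimmest array of each group, an alternative chosen after seeing the data.

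Of the lists, the unfolded protein and amino acid stress genes rose with hairpin 1 (camera adjusted p = 1.82e-05). Of 26 measured members 7 rose, or 9 adjusted over the list alone. They included Chac1, Ddit3, the folate enzyme Mthfd2 (0.84) and the cystine transporter Slc7a11 (0.82). The list's adjusted p was 0.0106 with an estimated correlation. The hypoxia and glycolysis list rose (camera adjusted p = 2.84e-04, and 0.0106 with an estimated correlation), with 4 of 22 members called, also 4 adjusted over the list alone. These were Ndrg1 (0.75), adrenomedullin (Adm, 0.61), lactate dehydrogenase A (Ldha, 0.30) and the glucose transporter Slc2a1 (0.28). Adm lost the threshold in 12 of 20 alternatives. The WNT and NOTCH target list fell (camera adjusted p = 6.03e-04, and 0.0153 with an estimated correlation). Of its 12 measured members 3 fell, or 5 adjusted over the list alone. The 3 were the Wnt deacylase Notum (-0.93), the receptor Notch1 (-0.75) and cyclin D1 (Ccnd1, -0.34). The list had 30 members, and those measured include receptors and ligands such as Notch1 and Dll4. Hes1, Hey1 and Nrarp were measured but not among the 3, so the fall of the list does not stand for the output of either pathway.

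The interferon response list fell with hairpin 1 at the preset correlation (camera adjusted p = 0.0045). The call was lost with the alternative, at adjusted p = 0.186 with an estimated correlation. Of 22 members 4 fell, or 7 adjusted over the list alone: Usp18, at least 1.15-fold lower, the immunoproteasome subunit Psmb8, at least 1.44-fold lower, and the oligoadenylate synthetase genes Oas1g (-0.67) and Oasl2 (-0.49). The JAK-STAT3 list fell (camera adjusted p = 0.0157, and adjusted p = 0.0603 with an estimated correlation), with 4 of 25 members lower. Adjusted over the list alone, 3 members rose and 6 fell. The 4 were Lcn2, the gelatinase gene Mmp9 (-1.02), Bcl3 (-0.53) and Ccnd1. Lcn2 and Mmp9 weighed heavily in the list, whose median was -0.0496 against a mean of -0.134. It was not tested without them. Bcl3 lost the threshold in 13 of 20 alternatives, Col18a1 in 9 and Oas1g in 8. The list of DDR1, collagen receptors and collagens fell (camera adjusted p = 0.014, and adjusted p = 0.183 with an estimated correlation) with 2 of 13 members lower, also 2 adjusted over the list alone, Col6a1 (-0.54) and Col18a1 (-0.26). In the L6 and tetraspanin list (camera adjusted p = 0.014, and adjusted p = 0.0814 with an estimated correlation), the member called, of 13 measured and also adjusted over the list alone, was Tm4sf1 itself. Without it, a test chosen after seeing the data, the list had a camera adjusted p of 0.0756.

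With hairpin 5, the largest rise was in Acta2, which encodes smooth muscle alpha-actin (log2 fold change 2.98, SE 0.162, adjusted p = 9.43e-13, limma, n = 3 against 3). Other Acta2 probes gave 1.71, 1.32 and 0.55, so the size of the rise is uncertain. Another Dcn probe gave 0.46, another Dhrs9 probe 0.36 and other Pkp2 probes 0.97 and 0.23. Another Tfap2c probe gave -0.51. The enteric smooth muscle actin gene Actg2 was at least 2.08-fold higher (adjusted p = 1.01e-06). Prl2c3 (1.73), Prl2c4 (1.56), the natriuretic peptide gene Nppb (1.14, SE 0.106, adjusted p = 4.5e-08) and the pentraxin gene Ptx3 (1.05) rose. The proteoglycan gene Dcn (0.95), the transcription factor gene Mycl (0.92), the retinol dehydrogenase gene Dhrs9 (0.83) and the desmosomal gene Pkp2 (0.83) rose as well. Among the falls were Pi16 (-1.71), Chst1 (-1.54), Mmp9 (-1.45, SE 0.0848, adjusted p = 3.26e-12), Lcn2 (-1.41, SE 0.0775, adjusted p = 9.43e-13), Plvap (-1.39) and Tfap2c (-1.33). Serpinf1, which encodes pigment epithelium-derived factor, fell by 1.21 and the adipogenesis gene Medag by 1.21. The coagulation factor gene F5 was at least 1.54-fold lower (adjusted p = 0.00245). With hairpin 5, Pi16, Chst1 and Serpinf1 were detected on 1 of 3 arrays and Tfap2c on 2 of 3, and Dcn, Mycl and Dhrs9 were detected on 2 of 3 scramble arrays. The sizes and the order of these changes depend on the background. Across 20 alternatives the change of Pi16 ran from -2.15 to -0.60 and that of Chst1 from -2.13 to -0.55, past the threshold in each.

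Hairpin 5 changed 290 genes (3.52%) at an adjusted p under 0.05 in limma, of which 110 rose and 180 fell, and 16 had a log2 change of 1 or more. The arrays of the 2 groups did not overlap for 20.8% of genes, against 10% by chance. The count was 153 without scramble replicate 1, 145 without scramble replicate 3 and 153 without hairpin 5 replicate 1. It was 170 with no detection filter, and 100 without the dimmest array of each group, chosen after seeing the data.

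The WNT and NOTCH target list fell with hairpin 5 (camera adjusted p = 0.00371, and 0.0318 with an estimated correlation). Of 12 members 3 fell, or 5 adjusted over the list alone, and these were again Notum (-0.90), Notch1 (-0.57) and Ccnd1 (-0.31). The JAK-STAT3 list fell (camera adjusted p = 0.00461, and 0.0318 with an estimated correlation), with 4 of 25 members lower, namely Mmp9, Lcn2, Ccnd1 and Cebpb (-0.24). Mmp9 and Lcn2 weighed heavily in it, since the median of the list was -0.0744 against a mean of -0.166. The list was not tested without them. Adjusted over the list alone, 2 of its members rose and 6 fell. Cebpb lost the threshold in 13 of 20 alternatives and Ccnd1 in 9. The cholesterol and fatty acid synthesis list fell (camera adjusted p = 0.0202, and adjusted p = 0.0933 with an estimated correlation). The elongase gene Elovl6 (-0.46) and the sterol synthesis genes Msmo1 (-0.42) and Sqle (-0.27) were the 3 of 24 members that fell, while 5 fell and 1 rose adjusted over the list alone. Sqle lost the threshold in 13 of 20 alternatives and Msmo1 in 8. With hairpin 1 that list had 1 member higher and 2 lower, in both adjustments (camera adjusted p = 0.293). The YAP/TAZ and SRF target list rose with hairpin 5 (camera adjusted p = 0.0255, and adjusted p = 0.0915 with an estimated correlation). The matricellular genes Ccn2 (0.69) and Ccn1 (0.54) rose, and the ectonucleotidase gene Nt5e fell by 0.69. Ccn1 lost the threshold in 13 of 20 alternatives. Adjusted over the list alone, 3 of 17 members rose and 1 fell. With hairpin 1, Ccn2 (0.39) rose and Nt5e (-0.34) fell, or 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.506). Camera did not call the other lists of hairpin 1 with hairpin 5. In the stress list (adjusted p = 0.743) Chac1 rose by 0.40 while Xbp1 (-0.58) and Slc7a5 (-0.35) fell, or 2 higher and 3 lower adjusted over the list alone. In the DDR1 list (adjusted p = 0.213) Col6a1 (-0.65) fell, and in the L6 and tetraspanin list (adjusted p = 0.14) Tm4sf1 fell, each also adjusted over the list alone. Of the hypoxia (adjusted p = 0.659) and interferon (adjusted p = 0.776) genes limma called 0, also adjusted over the list alone, with 3 and 5 at an unadjusted p under 0.05.

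Without scramble replicate 2, camera called 2 lists with hairpin 5 in place of 4.

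Both hairpins changed 143 genes in the same direction. The shared falls were led by Plvap, Chst1, Tfap2c, Pi16, Lcn2, Tm4sf1 and Mmp9, with the values given above. Serpinf1 (-1.01 with hairpin 1 and -1.21 with hairpin 5), Notum and the transcriptional co-activator gene Eya2 (-0.84 and -0.86) followed. The shared rises were led by Prl2c3, Prl2c4, Nppb (0.99 and 1.14) and Ptx3 (0.80 and 1.05, with another probe at 0.47 and 0.86). Gsta1 (1.51 and 0.75), the kinase gene Pak3 (0.79 and 0.69) and Gclm (0.95 and 0.62), which encodes the modifier subunit of glutamate-cysteine ligase, rose with both. Crybg1 (0.62 and 0.59) and the chemokine gene Cxcl16 (0.83 and 0.58) did so too. Havcr2 passed narrowly with hairpin 5 (adjusted p = 0.0442) and lost the threshold in 16 of 20 alternatives, and Eya2 lost it in 8 with hairpin 1 and 9 with hairpin 5. Eya2 was detected on 2 of 3 arrays with hairpin 1 and 1 of 3 with hairpin 5.

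Of the shared genes, 64 rose and 79 fell, where independent lists of these sizes would share 3.32 and 5.08. In opposite directions limma called 0 genes with both hairpins, where 8.53 would be shared by independent lists. Both comparisons used the same scramble arrays. In 50 simulations with no gene changed, the hairpins shared 0 calls. All arrays were drawn anew there, scramble included, so peculiarities of the real scramble arrays were not tested. Without planted changes, a count near 0 was fixed in advance. Across genes, which are not independent replicates, the fold changes of the hairpins correlated at r = 0.621, against 0.499 in the simulations, and their covariance was 0.032 against 0.0118. The 3 scramble arrays were not divided between the hairpins, so part of the excess may come from them. The shared count was 79 without scramble replicate 1, 70 without scramble replicate 3 and 92 without hairpin 5 replicate 1. It was 83 with no detection filter and 53 without the dimmest array of each group.

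**Figure D2:**
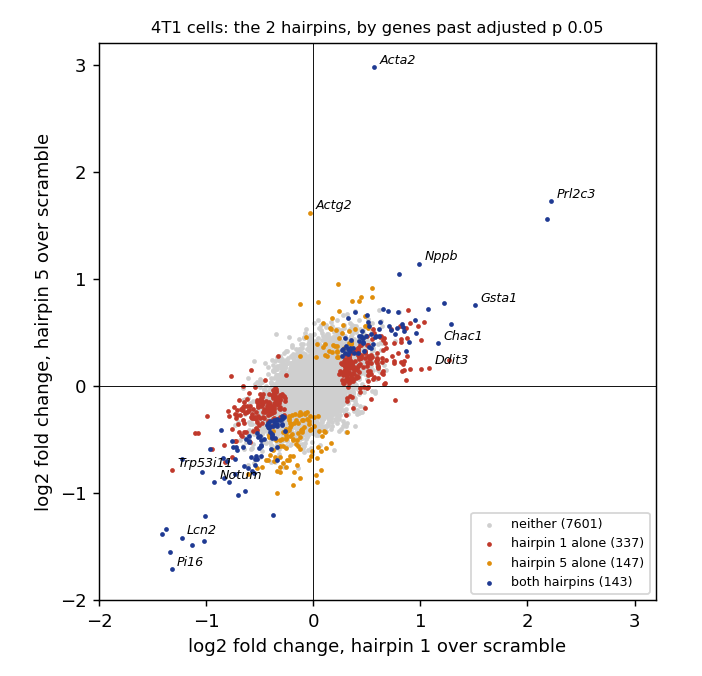
Log2 fold change over scramble with hairpin 1 (horizontal axis) and hairpin 5 (vertical axis), with a point for each of 8228 genes coloured by the comparison in which it was called, and fitted values for genes such as Actg2 that were undetected in a group. The 143 genes called with both hairpins lie in the lower left and upper right, from Pi16 and Lcn2 to Prl2c3, while Acta2 lies far above the rest for hairpin 5.

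The other 14 lists were not called by camera with either hairpin. Inflammatory and NF-kB targets included 5 members that rose and 1 that fell of 20 with hairpin 1, or 6 and 2 adjusted over the list alone. Ptgs2 (0.90, detected on 1 of 3 scramble arrays), Cxcl5 (0.85) and Cxcl16 rose there while Lcn2 fell. With hairpin 5, 2 rose and 2 fell, or 2 and 5 adjusted over the list alone. Of 21 p53 targets 4 rose, among them Cdkn1a (0.60), and 2 fell, among them Gadd45a (-0.56), with hairpin 1, or 5 and 2 adjusted over the list alone. With hairpin 5, Gadd45a (-0.81) and Sesn1 (-0.65) fell, 2 genes in both adjustments. Of 23 immediate early and heat shock genes 4 rose, among them Ier3 (0.65) and Jun (0.51), and 2 fell with hairpin 1, or 6 and 2 adjusted over the list alone. Dusp1 (0.41) rose and Phlda1 (-0.32) fell with hairpin 5, where Phlda1 lost the threshold in 13 of 20 alternatives, with the same counts adjusted over the list alone. Of 18 proteases and inhibitors Mmp10 (0.64) rose and 4 fell with hairpin 1, including Mmp9 and Ctsl (-0.49), and 3 fell with hairpin 5, with the same counts adjusted over the list alone.

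Of 20 TGF-beta and BMP targets, Tgfbi was at least 1.3-fold lower with hairpin 1 and at least 1.31-fold lower with hairpin 5, and Tgfbr1 (-0.58) fell with hairpin 5. These were 1 and 2 genes, also adjusted over the list alone. Of 16 MHC class I and antigen processing genes, Psmb8 fell with hairpin 1, or 2 genes adjusted over the list alone, and limma called 0 with hairpin 5, with 3 at an unadjusted p under 0.05. Of 12 mesenchymal genes, Acta2 rose with hairpin 1 (0.57, lost in 8 of 20 alternatives, with other probes at 0.51, 0.43 and -0.11) and hairpin 5, and Mmp14 (-0.33) fell with hairpin 5, with the same counts adjusted over the list alone. Of 27 E2F targets Fen1 (-0.45) fell with hairpin 1, the same adjusted over the list alone, and limma called 0 with hairpin 5, with 3 at an unadjusted p under 0.05. Of 11 stem cell, 10 epithelial, 19 G2/M and 29 oxidative phosphorylation genes, limma called 0 with either hairpin, while 2, 2, 4 and 1 had an unadjusted p under 0.05 with hairpin 1 and 1, 3, 2 and 5 with hairpin 5. Adjusted over the list alone, 1 stem cell gene rose with hairpin 5. The stem cell list had 24 members and the epithelial list 32, and genes such as Nanog, Sox2, Cdh1 and Epcam were not among those measured. Markers of other cell types were mostly undetected, with 3 leukocyte and 3 stromal markers measured. The granulocyte gene S100a8 fell by 0.31 with hairpin 1, where adjusted over the list alone 1 leukocyte marker also rose, and the fibroblast marker Dcn rose with hairpin 5, in both adjustments. The lowest camera adjusted p of these lists was 0.0514 with hairpin 1, for the MHC list, and 0.0972 with hairpin 5.

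For some lists the median, the mean and the test did not share a sign. These were the protease, mesenchymal and stromal lists with hairpin 1, and the stress, p53, mesenchymal and stromal lists with hairpin 5. Between the hairpins they were the epithelial, TGF-beta, leukocyte, mesenchymal and stromal lists. With TM4SF1 in 4TO7 they were the DDR1, G2/M, stem cell, WNT and protease lists, and between the lines the hypoxia and immediate early lists. None of these lists was called by camera in the comparison concerned.

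Direct comparison of the hairpins separated some of these changes. Against hairpin 5, hairpin 1 gave higher Atp13a4 (1.02, SE 0.17, adjusted p = 8.51e-04, limma), Dennd10 (0.93, adjusted p = 3.15e-06), Ddit3 (0.92, adjusted p = 2e-04), Rapsn (0.90, adjusted p = 0.0292) and Ccn5 (0.86, adjusted p = 0.0114). Relative to scramble, Dennd10 hardly moved with hairpin 1 (0.03) and was lower with hairpin 5 (-0.90). Acta2 was lower by 2.41 on the log2 scale (log2 difference -2.41, SE 0.162, adjusted p = 2.54e-10), Actg2 was at least 2.13-fold lower, and the potassium channel gene Kcnk6 (-0.86), Lrp11 (-0.83) and Ly6e (at least 1.45-fold) were lower too. Other probes gave -1.28, -0.81 and -0.66 for Acta2, 0.90 and 0.49 for Dennd10, 0.32 and 0.20 for Rapsn and -0.39 for Kcnk6, so these sizes are uncertain. Rapsn lost the threshold in 9 of 20 alternatives, and Rapsn, Ccn5 and Lrp11 were each detected on 2 of 3 arrays of the dimmer group. Tm4sf1 differed by 0.36 (95% interval -0.04 to 0.76, adjusted p = 0.441, limma), which the test did not resolve. The stress list was higher with hairpin 1 than with hairpin 5 (camera adjusted p = 2.8e-12, and 7.99e-04 with an estimated correlation). Of its 26 members 7 were higher, while adjusted over the list alone 9 were higher and 1 lower. The hypoxia and glycolysis list was also higher (camera adjusted p = 3.39e-04, and 0.0113 with an estimated correlation), with 3 members called or 6 adjusted over the list alone.

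Inflammatory targets were higher with hairpin 1 than with hairpin 5 (camera adjusted p = 6.82e-04, and adjusted p = 0.136 with an estimated correlation). The chemokine Cxcl1 (0.57) and Traf1 (0.41) were higher and Vcam1 (-0.41) was lower, or 7 higher and 1 lower adjusted over the list alone. Interferon genes were lower (camera adjusted p = 0.00163, and adjusted p = 0.167 with an estimated correlation), with Gbp3 (-0.67) called and 3 lower adjusted over the list alone. Gbp3 and Traf1 each lost the threshold in 14 of 20 alternatives. In all, 153 genes differed in limma (103 higher and 50 lower with hairpin 1), and groups were apart for 17.1% of genes against 10% by chance. The count was 100, 80 and 90 without hairpin 1 replicates 1, 2 and 3, and 92 without hairpin 5 replicate 1. The other 19 lists had camera adjusted p from 0.0667 to 0.974. The gene count was 101 with no detection filter, 84 with no variance trend and 42 without the dimmest array of each group.

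**Figure D3:**
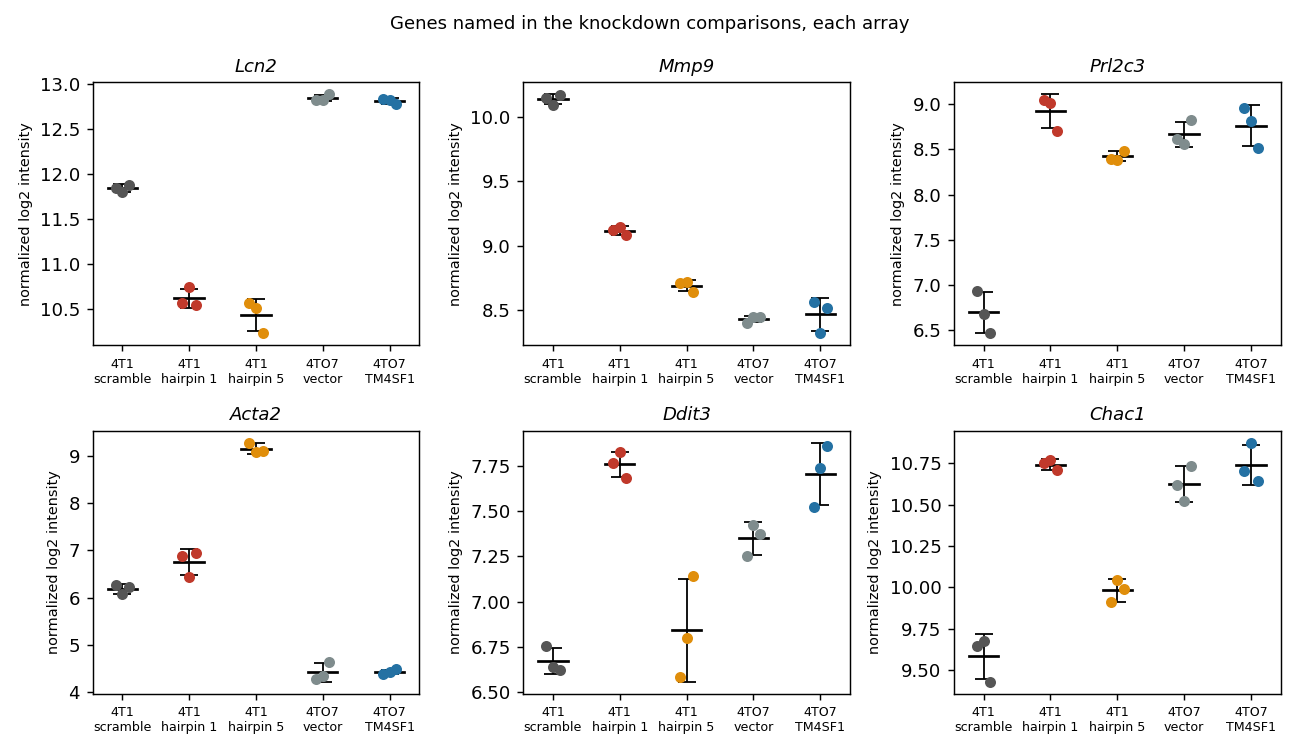
Normalized log2 intensity (vertical axes) of Lcn2, Mmp9, Prl2c3, Acta2, Ddit3 and Chac1 on each array by group (horizontal axes), with points for arrays, thick bars for means and error bars for 1 SD (n = 3). Lcn2 and Mmp9 lie lower and Prl2c3 higher with both hairpins, Acta2 stands out with hairpin 5, and Ddit3 and Chac1 lie highest among 4T1 groups with hairpin 1.

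Introducing TM4SF1 into 4TO7 asked the converse question. The organic anion transporter gene Slco4a1 rose by 0.57 (SE 0.0894, adjusted p = 0.00429, limma, n = 3 against 3), and the aldehyde dehydrogenase gene Aldh3a1 rose by 0.50 (SE 0.0717, adjusted p = 0.00147). These were the 2 genes called, with 594 at an unadjusted p under 0.05 where chance would give 411.4. Slco4a1 had also risen with hairpin 1 (0.59, adjusted p = 9.59e-05) and hairpin 5 (0.46, adjusted p = 0.00231), and Aldh3a1 with hairpin 1 (0.57, adjusted p = 7.85e-06). The groups were apart for 12.7% of genes, against 10% by chance. Fitted on the compared arrays alone, or with no variance trend, limma called 0 genes, with 609 and 579 at an unadjusted p under 0.05. Without vector replicate 1 or TM4SF1 replicate 1 it called 1.

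The interferon response list was lower with TM4SF1 (camera adjusted p = 6.65e-08, and adjusted p = 0.0826 with an estimated correlation). Of 22 members, 21 had a negative log2 fold change, with a mean of -0.28, and the largest was that of Usp18 (-0.71, adjusted p = 0.293). Limma called 0 of them over all genes, 8 had an unadjusted p under 0.05, and 8 were lower adjusted over the list alone. The other 22 lists had camera adjusted p from 0.177 to 0.915, and limma called 0 of their members. Adjusted over the list alone, 2 inflammatory genes, 1 hypoxia gene and 1 p53 target were lower. Without vector replicate 2 or TM4SF1 replicate 1, camera called 2 lists. No gene shared by the hairpins was called in the opposite direction in 4TO7: limma gave 0 reciprocal genes, where 0.0192 would be expected by chance with so few calls in 4TO7. At an unadjusted p under 0.05 there were 22 of the 143 shared genes in 4TO7, of which 4 went the opposite way and 18 the same way. All shared genes together had the opposite sign in 30.1% of cases. Some of them, such as Plvap, Chst1 and Gsta1, were undetected on every 4TO7 array, so their signs there say little. Over all 8228 genes, changes in 4TO7 also correlated weakly with those of hairpin 1 (r = 0.133) and hairpin 5 (r = 0.146).

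**Figure D4:**
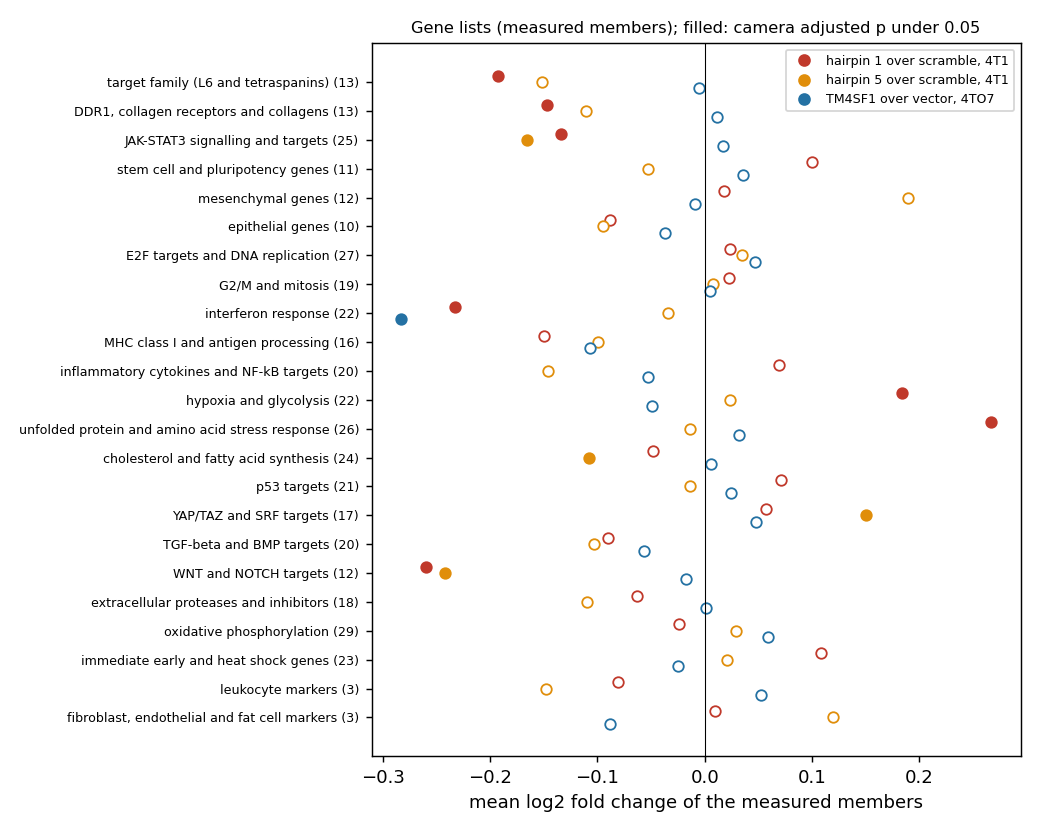
Mean log2 fold change of the measured members (horizontal axis) of each of 23 gene lists (vertical axis, members measured in parentheses) for hairpin 1, hairpin 5 and TM4SF1, with filled points for lists past a camera adjusted p of 0.05. The stress and hypoxia lists lie highest for hairpin 1, the WNT and NOTCH target list lies low for both hairpins, and interferon genes lie lowest for TM4SF1.

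The control groups of the lines differed far more widely. Relative to scramble 4T1, vector 4TO7 expressed the endothelial proteoglycan gene Esm1 at least 60.8-fold higher, the cyclophilin gene Ppic at least 50.2-fold, Xlr4a at least 20.4-fold, the lipid phosphatase gene Plpp3 at least 16.5-fold and Tbcel at least 16.1-fold higher. Brain creatine kinase (Ckb) was at least 140-fold lower, the fatty acid desaturase Fads1 at least 74.4-fold, Scarf2 at least 48-fold, fibulin 1 (Fbln1) at least 20.3-fold and Tmem185b at least 18.3-fold lower. Other probes gave smaller log2 differences, 4.18 for Ppic and -1.90 and -0.77 for Fbln1, so these sizes are uncertain. In limma, 3977 genes passed (2103 higher and 1874 lower in 4TO7), of which 762 had a log2 change of 1 or more, and the groups were apart for 57% of genes against 10% by chance. The vector type differed between these groups along with the line, so line and vector cannot be told apart here.

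Stress genes were higher in 4TO7 (camera adjusted p = 2.24e-06, and 0.0128 with an estimated correlation), with 18 of 26 higher and 1 lower in both adjustments, led by Mthfd2 (1.98) and Herpud1 (1.53). Inflammatory targets were higher (camera adjusted p = 2.24e-06, and 0.0425 with an estimated correlation), with 15 of 20 higher and 2 lower in both adjustments. Among them were the colony-stimulating factor gene Csf3 (3.10) and the chemokine genes Cxcl5 (2.82) and Cxcl1 (2.24). Interferon genes were higher (camera adjusted p = 0.00882, and adjusted p = 0.205 with an estimated correlation), with 13 of 22 higher and 1 lower, or 14 and 1 adjusted over the list alone. Epithelial genes were lower (camera adjusted p = 0.0107, and adjusted p = 0.192 with an estimated correlation), with 5 of 10 lower in both adjustments, including keratin 18 (Krt18, -2.37) and Spint1 (-1.26). TGF-beta and BMP targets were lower (camera adjusted p = 0.0282, and adjusted p = 0.178 with an estimated correlation), with 3 of 20 higher and 9 lower in both adjustments, including Pdgfb (-2.96, detected on 1 of 3 vector arrays). The other 18 lists had camera adjusted p from 0.0687 to 0.982.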

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

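The tests for markers of other cells and for the extent of Tm4sf1 loss were chosen only after the result was seen. Array brightness as a covariate was chosen after seeing the data. Of the 38 genes named as the largest or shared changes of the knockdowns, members named only from lists not included, 13 differed between the hairpins by limma's test of the difference itself. Acta2 (-2.41, adjusted p = 2.54e-10), Actg2 (fitted value -1.64, adjusted p = 2.8e-06) and Dcn (-0.73, adjusted p = 0.00673) were lower with hairpin 1. Atp13a4 (1.02, adjusted p = 8.51e-04), Ddit3 (0.92, adjusted p = 2e-04), Aldh1l2 (0.85, adjusted p = 1.23e-04), Medag (0.84, adjusted p = 3.65e-05) and Chac1 (0.76, adjusted p = 3.15e-06) were higher with hairpin 1. So were Gsta1 (0.75, adjusted p = 0.0127), Slc14a1 (0.71, adjusted p = 0.00255), Prl2c4 (0.62, adjusted p = 0.00673), Prl2c3 (0.50, adjusted p = 0.0348) and Mmp9 (0.43, adjusted p = 0.00582). Prl2c3 lost the threshold in 9 of 20 alternatives. Other probes gave smaller differences for Acta2 (-1.28, -0.81 and -0.66), Aldh1l2 (0.42) and Dcn (-0.37), and 0.83 and 0.25 for Slc14a1.

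The first pattern weighed was the rise of Acta2 and Actg2 with hairpin 5. The tables argue against a single array as the cause, since the lowest log2 rise of Acta2 without any 1 of the 6 arrays was 2.91. For fibroblasts or smooth muscle cells in the cultures, 0 of 9 markers (Col1a1, Col1a2, Col3a1, Lum, Thy1, Fap, Myh11, Des and Cnn1) were well above background on all 3 hairpin 5 arrays. Of the 3 stromal markers measured, Dcn, another fibroblast gene, rose by 0.95, while the other 2, Pdgfra and Pdgfrb, had negative log2 fold changes and were not called. The silent markers argue against such cells only if their probes respond, which these arrays do not establish, since none passed the detection filter. The extent of Tm4sf1 loss stays open, because Tm4sf1 differed between hairpins by 0.36 with a 95% interval of -0.04 to 0.76. An effect of hairpin 5 on other transcripts stays open and untested.

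The second pattern was the rise of the unfolded protein and amino acid stress list with hairpin 1. Without any 1 of the 6 arrays the list's mean log2 fold change kept at least 91.8% of its value, which argues against a single array as the cause. With array brightness as a covariate it was 102% of its value, which argues against brightness. Genes of 4TO7 that scramble arrays lack had a median log2 change of -0.0205 with hairpin 1 (11 genes, quartiles -0.0711 and 0.0665), which argues against 4TO7 material in those samples. Differences in culture between the groups cannot be separated from the hairpin in this design and stay open, as does an effect of hairpin 1 on other transcripts.

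The third pattern was that genes shared by the hairpins mostly had the same sign in 4TO7 with TM4SF1, 69.9% of 143 genes. Over all genes, too, changes in 4TO7 correlated weakly with those of each hairpin (r = 0.133 and 0.146). Leaving out each 4TO7 array gave 67.8% to 70.6%, which argues against a single 4TO7 array. Mean signal was lower in the treated groups of both lines, at 307.3 and 314.8 against 343.5 in 4T1 and 300.3 against 354.7 in 4TO7. Within groups its SD ran from 41.1 to 94.4. With array brightness as a covariate in the 4TO7 changes the share was again 69.9%, which argues against a linear effect of brightness there. The shared genes themselves came from the fit without the covariate, so brightness is not excluded for them. A partial swap of vector and TM4SF1 arrays stays open: another split of the 6 arrays (vector 1, vector 3 and TM4SF1 1 against the rest) called 7 genes, more than the 2 of the labelled split. The 7 fell short of the bound of 10 genes set beforehand, but that bound ignored that the labelled split might itself call so few. Tm4sf1 showed no gain at its probe, which may lie outside the transduced sequence, so whether these arrays differ in TM4SF1 as labelled stays open.

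For each comparison of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. For genes with hairpin 1, 1 split reached the real value of 480 and the highest other was 0. With hairpin 5, 1 split reached 290 and the highest other was 1. For hairpin 1 against hairpin 5, 1 split reached 153 and the highest other was 1. For TM4SF1 in 4TO7, 2 splits reached 2 and the highest other was 7. Between the lines, 1 split reached 3977 and the highest other was 0. For lists called, 1 split reached the 7 of hairpin 1 and 1 the 4 of hairpin 5, each with a highest other of 2, while 5 splits reached the 1 of TM4SF1 and the highest other was 2. Of 100 splits of the 9 arrays of 4T1, 1, the real one, reached the 143 shared genes. That speaks only against no difference at all among the groups. The 2 other splits that kept the scramble arrays together reached 105 at most, with a median of 103. The 97 splits that did not reached 38 at most. Most of the count thus goes with scramble against the rest, so peculiarities of the scramble arrays are not excluded. For reciprocal genes, the real value was 0 and the highest other was 0. Any split reaches a count of 0, so that 100 of 100 did says nothing about chance.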

How the results depend on the processing

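The brightness covariate, the omission of the dimmest array of each group and the target family list without Tm4sf1 were chosen after seeing the data. Under no background correction, the deposited normalized table, an offset of 50, cyclic loess and median scaling, all gene counts stayed within 1.5 times their value, and all 21 list calls kept their direction and their call. Sizes moved more: without background correction the log2 change of Tm4sf1 was -0.73 with hairpin 1 and -0.90 with hairpin 5, and over all alternatives the fitted rise of Actg2 with hairpin 5 ran from 0.53 to 1.98. Of 255 pairs of a named gene and a comparison, refitted 5100 times under alternatives, 4624 fits kept the threshold, 476 lost it and 0 reversed. With all probes, the probe of lowest adjusted p stood for its gene, so weaker probes that disagreed were not counted. Another Acta2 probe, for example, gave -0.11 with hairpin 1.

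With no detection filter, in which 18312 genes were tested, limma called 318 genes with hairpin 1, 170 with hairpin 5, 101 between hairpins and 83 shared. With only the compared arrays it called 0 in 4TO7 with TM4SF1 (609 at an unadjusted p under 0.05). With no variance trend it called 84 between hairpins and 0 in 4TO7 (579 at an unadjusted p under 0.05). Without the dimmest array of each group, which leaves fewer arrays, it called 183, 100 and 42 genes and 53 shared. Camera with an estimated correlation called 3 lists with hairpin 1, 2 with hairpin 5 and 0 with TM4SF1, while fry, which asks another question, called 11 and 8 with the hairpins. Where none is named here, the cause was not tested.

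Leaving out each array gave 273 to 355 genes with hairpin 1, 145 to 258 with hairpin 5, 80 to 161 between hairpins, 1 to 3 in 4TO7 with TM4SF1 and 70 to 128 shared. Lists called ran from 2 to 6 with hairpin 5 and from 1 to 2 with TM4SF1. The log2 change of Tm4sf1 in 4TO7 ran from -0.075, without vector replicate 2, to 0.34.

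Replicate numbers did not pair the arrays (residual correlations of -0.146 to 0.0631 over 12 pairs). With them as a block, limma called 394 genes with hairpin 1, 213 with hairpin 5, 114 between hairpins and 2 in 4TO7 with TM4SF1. The block was coded within each line, so between the lines that fit compared the levels of replicate 1. Its 2776 calls there thus answer another question than the 3977 of the main fit. The slide as a block was not run, since the slide is not given in the sources used here. Signal over background limits dim genes, and folds are given as bounds where a gene was undetected on all arrays of a group.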

Other observations

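The tests of the shared genes as sets in 4TO7 and of NRF2 targets were chosen only after the result was seen.

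The following genes were picked because they rose with hairpin 1. Slc7a11 and Chac1 belong to the stress list. Gsta1 (1.51), Gsta2 (1.04) and Gclm (0.95) rose, with the cystine transporter Slc7a11 (0.82) and the glutathione-degrading enzyme gene Chac1 (1.16). A candidate explanation is the transcription factor NRF2. Its other targets (15 measured, without those already named) were higher at the preset correlation of camera (adjusted p = 0.00861, median log2 fold change 0.272, 3 called higher), but the adjusted p was 0.0628 with an estimated correlation. With hairpin 5 and with TM4SF1 in 4TO7 the estimated correlation gave 0.172 for each, so the question stays open.

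The reciprocal hypothesis, that genes shared by the hairpins move the opposite way when TM4SF1 is introduced, was tested on the shared genes as sets. The 79 fallen genes were lower as a set in 4TO7 with TM4SF1 (camera adjusted p = 0.0216 with an estimated correlation, 53 negative), and the 64 risen genes were higher (0.00939, 47 positive). The medians were small, at -0.0573 and 0.078 on the log2 scale. Taken as labelled, both directions are opposite to the prediction. Tm4sf1 showed no detectable gain at its probe (0.14, adjusted p = 0.933) and a partial swap of these arrays stays open, so the hypothesis is not settled.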
